A study of Mus musculus with 6 samples.

How the data were processed

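RNA from sorted mouse bone marrow cells (B220+CD43+) was measured on 6 Illumina BeadChip arrays, 3 labelled Fnip1-null and 3 labelled wild type. The deposited table of scanner output holds, per the file headers, a signal intensity and a detection p-value for each probe on each array. No normalization is recorded for these intensities, and the detection p-value deposited by the authors was used as given. A second deposited table, the series matrix, holds the authors' processed values, which were taken as log2 from their range. Its columns have the same lowest and highest value (0.28 and 15.26) and nearly the same median (2.46). The background correction behind it, its offset and its log base are not given in the sources used here. Each of its columns had the same order of probes as exactly 1 scanner column, in the group that the labels give, so both tables name the groups alike. The submitters' processing notes name the tool affy without a version. All 6 signal columns and 6 detection columns were used.

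Scanner columns carry the genotype and a number of unstated meaning but no replicate number. The columns labelled Fnip1-null, and not those labelled wild type, also carry the words LPAB - Yugioh, whose meaning is not stated. Arrays are called A, B and C within a group, in the order of their columns. The shared order of probes could link each array to a replicate number, but this link was not used here. Intensities were corrected for background by normexp with the background estimated from the detection p-values and an offset of 16, quantile normalized between arrays and put on a log2 scale (neqc in limma 3.58.1, R 4.3.3). The 18172 probes with a detection p under 0.05 on at least 3 of the 6 arrays were tested with lmFit and eBayes, and p-values were adjusted by Benjamini-Hochberg over these probes. A call is an adjusted p under 0.05. By probe, 1401 were higher and 1182 lower, and 5174 had an unadjusted p under 0.05. A positive log2 fold change means higher on the arrays labelled Fnip1-null. Intervals at 95% come from the moderated standard error with 9.17 degrees of freedom.

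Probes were named through the platform annotation of 2016. Of 45281 probes 34885 had 1 gene symbol, 18 had several and 10378 had none in the table used here. Symbols were updated to those of a RefSeq gene table (assembly GRCm38, patch 6) through the gene number for 34807 probes and the accession for 11, and 67 kept the annotation's symbol. That table also gave the order of genes along chromosomes. Of the tested probes 2860 had no single gene name, 530 of them called. A gene is represented by its probe of highest mean, and other tested probes of the gene can show a smaller change. Of 3818 genes with more than 1 tested probe, 9 had called probes in both directions. A probe that is not detected on every array of its dimmer group has only a bound there, a rule widened after the values were seen from probes detected on no array of it. The fold is then given as at least the bright group's mean over the dim group's mean of, per array, the higher of the lowest detected signal and the probe's own. Probes of near-identical family members can share signal.

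The main tests, the 39 gene lists and the rule for named genes were fixed before the data were examined. Tests and blocks chosen later are named as such. Named genes were Fnip1, the 12 largest rises and 12 largest falls among called genes with the groups fully separated, detection on all arrays of the higher group and a symbol that is more than a clone number, up to 4 members of lowest p per list, and a fixed set (among them Flcn, Fnip2, Rragc, Rragd, Gpnmb, Ppargc1a, Myc, Il7r, Rag1, Dntt, Igll1, Vpreb1, Il2ra, Cdkn1a and Mki67). Not all of the list members are printed: those shown were picked after the results and the alternatives were seen, mostly for keeping their call when settings changed, so they look steadier than the named genes as a whole. All 174 tested named genes besides Fnip1 were followed under the alternatives, of which 110 were called. Mki67 had no probe named for it in the table used here. Lists were tested with camera (preset correlation 0.01, and an estimated one) and fry, adjusted over the lists. Single genes were also counted after adjustment over the list alone. Fnip1 was also tested by an exact two-sided permutation test. All 10 splits of the 6 arrays into 3 and 3 were fitted in the same way, a test chosen after the results were seen.

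The fit was tested on simulated arrays for this comparison, made from the 18172 tested probes' means. Spreads were drawn from the distribution fitted to all tested probes, with independent noise. In the simulation 67, 67 and 66 probes were changed by 0.5, 1 and 2 on the log2 scale. The fit recovered 16.4%, 86.6% and 100% of these, with 9 false calls among 144. Small changes were thus mostly missed in the simulation. The real comparison called 2583 probes, which makes its adjusted threshold less strict, so these shares do not carry over to it. Alternatives covered background correction, normalization, the series matrix values, the filter, the variance model, array weights, thresholds, the probe that represents a gene, list membership and each array left out. A block on the replicate number was fitted only on the series matrix values, whose columns carry the numbers, and not on the main values. A block on sex, read from whether Xist is detected, was added after the data were seen. A block on the BeadChip was not run, since the table names none.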

Results

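Total RNA from mouse bone marrow cells sorted as B220+CD43+, a gate that holds early B-lineage cells and that the labels call pre-B cells, was hybridised to 6 single-colour Illumina BeadChip arrays. According to the labels, 3 arrays held RNA from Fnip1-null mice and 3 from wild-type mice. Fnip1 encodes folliculin-interacting protein 1, a partner of the tumour suppressor folliculin, which acts with the energy sensor AMPK and with nutrient signalling at the lysosome. Each array reported 45281 probes, of which between 17442 and 18294 were detected at a p under 0.05, and the median signal per array lay between 40.5 and 44.3. With 3 arrays per group, the number of arrays limits the precision. Scanner columns carry a number each, which may be that of an animal, and those of the A arrays of both groups follow each other, as littermates' might. What these numbers mean is not stated, so p-values measure the spread between these samples. Array A of each group lacked Xist (4.22 and 4.62) and held the Y-linked Eif2s3y (9.45 and 9.92), while arrays B and C had Xist between 9.50 and 10.78 and Eif2s3y between 4.22 and 4.28. Each group thus holds male and female RNA, in the same proportion.

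The level of Fnip1 itself was examined first, since it checks the labels. Fnip1 signal was higher, not lower, on the arrays labelled Fnip1-null. The brightest of its probes averaged 10.01 ± 0.04 (log2, SD, n = 3) on the arrays labelled Fnip1-null and 9.06 ± 0.14 (SD, n = 3) on those labelled wild type, a 1.94-fold difference (95% interval 1.63 to 2.30, limma adjusted p = 0.000663). A pair of other detected probes differed in the same direction, by 0.88 and 0.78 on the log2 scale, with limma adjusted p = 0.0085 and 0.00117. For each of these probes all 3 arrays of one group lay above all 3 of the other, and the exact two-sided permutation test gave p = 0.1, the smallest that 3 arrays against 3 allow. A further probe for Fnip1 was not well above background on any array. Neither the change made to the gene nor the position of the probes is given in the sources used here, and a probe outside the changed part checks nothing. The transcript level therefore does not bear out the genotype labels, and every direction below is that of the arrays labelled Fnip1-null against those labelled wild type.

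The main comparison asked which genes differ between the genotypes. Of 9679 genes tested, 762 were higher and 508 lower on the arrays labelled Fnip1-null (limma, adjusted p under 0.05), and 121 of the higher and 89 of the lower genes differed at least 2-fold. Nyx, which encodes the proteoglycan nyctalopin, was at least 192-fold higher by its brightest probe. It was detected on 3 arrays labelled Fnip1-null and 1 labelled wild type, and its other tested probe rose by a smaller 1.85 on the log2 scale. Hdc, the enzyme that makes histamine, rose 14.3-fold (95% interval 8.90 to 23.0) and the myosin light chain gene Myl10 14.3-fold (10.3 to 19.7). The potassium channel gene Kcnf1 was not well above background on any array labelled wild type and was at least 6.19-fold higher (adjusted p = 4.7e-06). The chemokine receptor gene Cxcr5 rose 6.30-fold, the proline dehydrogenase gene Prodh 6.12-fold, and its neighbour Dgcr6 5.25-fold. Hebp1, Rragd, the transferrin gene Trf, Ell3 and the adaptor gene Lat rose by 2.44, 2.44, 2.43, 2.42 and 2.42 on the log2 scale.

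Reln, which encodes the secreted glycoprotein reelin, was at least 46.5-fold lower (adjusted p = 7.38e-06) and the protamine gene Prm1 at least 16.7-fold lower, each detected on 2 of 3 arrays labelled Fnip1-null. The AMPK-related kinase gene Nuak1 stood at -4.11 on the log2 scale (-2.53 by its other tested probe) and the claudin gene Cldn10 at -3.09. Prg3, an eosinophil granule gene, and Klhl14 were not well above background on any array labelled Fnip1-null and were at least 8.44-fold and at least 3.65-fold lower there. The costimulatory receptor gene Cd40 fell by 2.47, Diras2 by 2.41, the Ras activator gene Rasgrp1 by 2.39, the purinergic receptor gene P2rx3 by 2.11 and the stearoyl-CoA desaturase gene Scd1 by 2.10, and the growth hormone gene Gh was at least 4.42-fold lower. Other tested probes of Cd40 stood at -2.11 and -0.93, and that of Rasgrp1 at -1.44. In total 3193 genes (33.0%) had all arrays of one group above all of the other, where chance gives 10%. Arrays of one group correlated at 0.989 or more over the tested probes and arrays of different groups at 0.976 or less. Leaving out 1 array moved the number of called genes from 1270 to as few as 731 (without array B labelled Fnip1-null) and 788 (without array B labelled wild type).

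**Figure D1:**
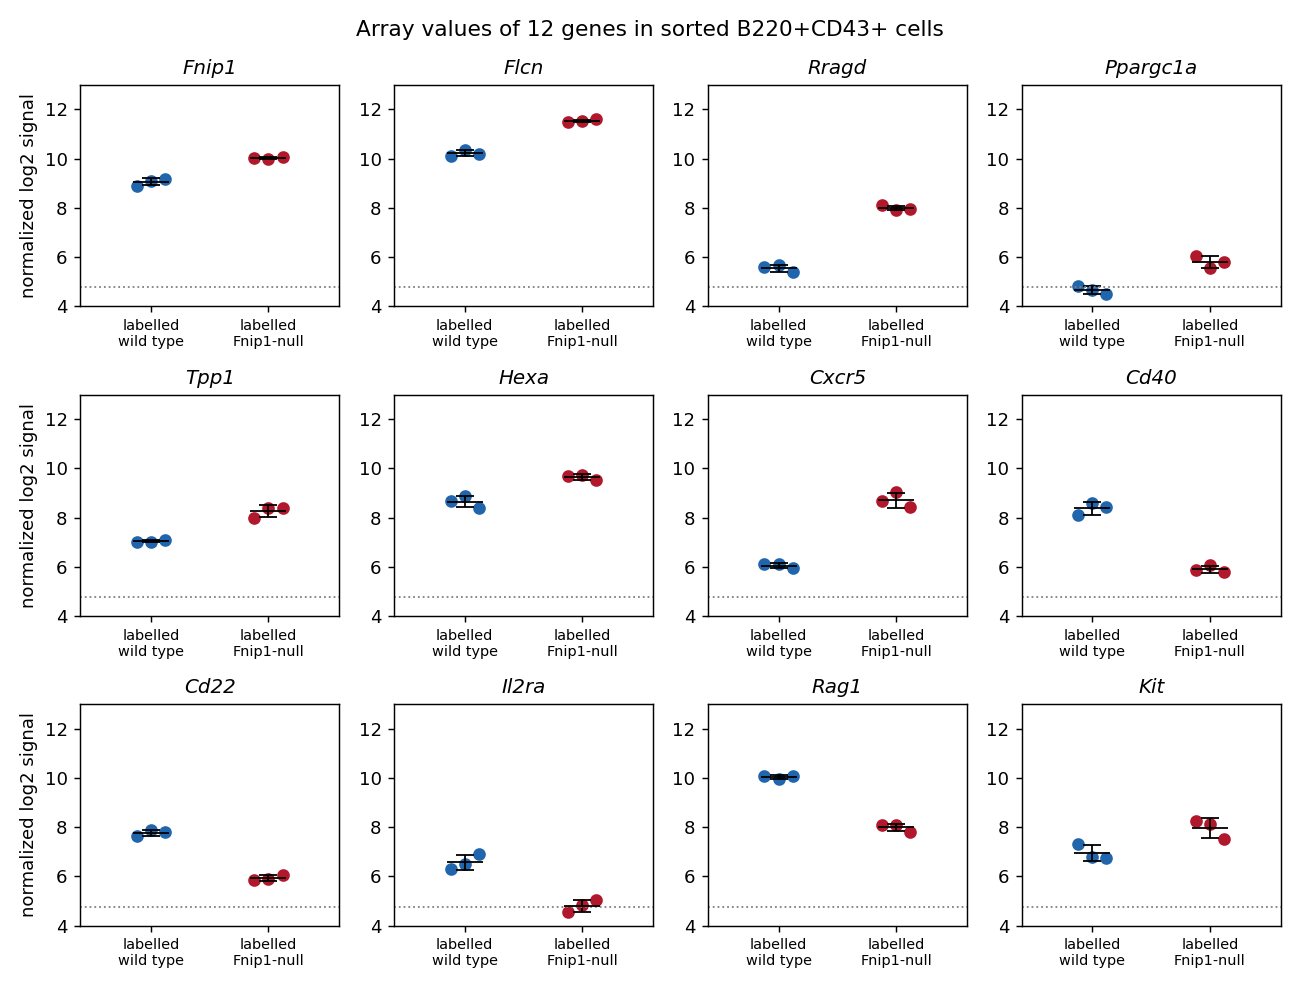
Normalized log2 signal (vertical axis, 4 to 13) of 12 genes on the 6 arrays. Points are arrays, the bar is the group mean with its SD (n = 3), and the dotted line is the mean over arrays of the lowest signal detected at a p under 0.05. Fnip1, Flcn, Rragd, Ppargc1a, Tpp1, Hexa, Cxcr5 and Kit are higher on all 3 arrays labelled Fnip1-null, and Cd40, Cd22, Il2ra and Rag1 are lower on all 3.

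Most measured genes of the folliculin pathway, and 13 of 40 lysosomal genes, were higher on the arrays labelled Fnip1-null. In the list of folliculin partners, Rag GTPases and TFE3 targets, 6 of 8 measured members rose and none fell, and 6 rose when adjusted over the list alone. Rragd, a Rag GTPase that recruits mTORC1 to the lysosome, rose 5.43-fold (95% interval 4.53 to 6.49), and Flcn, which encodes folliculin, rose 2.48-fold (SE 0.11 on the log2 scale, adjusted p = 7.88e-05). Ppargc1a, the coactivator of mitochondrial biogenesis, was at least 2.02-fold higher, and Gpnmb, a lysosomal glycoprotein gene and TFE3 target, was at least 1.47-fold higher. Rragc, another Rag GTPase gene, rose by only 0.42 on the log2 scale (limma adjusted p = 0.0478). It lost its call under 8 of 19 alternatives, 4 of them with 1 array left out. Fnip2 had 1 probe, which was not detected on any array. None of the lysosomal genes fell (15 rose adjusted over the list alone), and those that rose include those of the hydrolases Tpp1 (log2 fold change 1.23), Hexa (0.99), Gaa (0.76) and Neu1 (0.69). The medians of these lists were 0.61 and 0.22, and camera gave adjusted p = 3.31e-05 and 3.69e-05. With an estimated correlation the adjusted p = 0.189 for the folliculin list and 0.941 for the lysosome. Fry gave these lists adjusted p = 0.00099 and 0.0593. Of 28 autophagy genes 3 rose and 1 fell (the same counts adjusted over the list alone), and of 19 components and regulators of mTORC1 and AMPK 1 rose and 1 fell (1 and 2 over the list alone). Camera gave adjusted p = 0.915 for each of these lists.

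These list tests rest on a weak footing that belongs beside every list below. Camera with its preset correlation called 6 of the 39 lists, 3 higher and 3 lower, and none with an estimated correlation. The estimated correlation was -0.010 for the folliculin, 0.010 for the late pre-B and -0.10 for the Fnip1 neighbour list, near or below the preset 0.01. It was 0.20 for the lysosome, 0.39 for the cell cycle and 0.53 for the natural killer list. For the folliculin, late pre-B and Fnip1 neighbour lists the unadjusted camera p still rose with the estimate. It went from 8.5e-07 to 0.007, from 3.15e-06 to 0.0097 and from 0.0047 to 0.042. A correlation well above the preset thus does not account for the lost calls of these lists. When the 6 arrays were split into 3 and 3 in other ways, no gene passed, but camera with its preset correlation called between 2 and 11 lists. Each of these splits mixes the groups, so part of the difference between groups stays in its contrast and the rest adds to its spread. The lack of called genes was thus likely from the start, and the list calls are no pure measure of false calls. The p of the folliculin, the late pre-B and the Fnip1 neighbour lists was lower in the real split than in any other, although 1 other split called the folliculin list (lowest adjusted p = 0.0474) and 3 called the late pre-B list (0.00159). For the lysosome list, 4 of the 10 splits, the real one included, gave a p as low as the real split did, as did 4 for the natural killer list and 3 for the cell cycle list. Fry, which asks whether a list's genes move on balance one way and does not compare them with other genes, gave an adjusted p under 0.05 to 5 lists, and its mixed test to 28. The 5 were the folliculin (0.00099), Fnip1 neighbour (0.00145), late pre-B (0.0181), hypoxia and mitochondrial biogenesis lists (0.0442 each). Counts of called members move as well when 1 array is left out: those higher in the folliculin list from 6 to between 3 and 5, in the lysosome list from 13 to between 8 and 12, in the hypoxia list from 6 to between 3 and 5 and in the list of pre-B cell receptor signalling from 6 to between 2 and 4, and those lower in the late pre-B list from 9 to between 7 and 9. Higher counts ran between 1 and 3 for autophagy and antioxidant genes, 2 and 4 for p53 targets and 0 and 2 for apoptosis genes. For T cell markers they ran between 2 and 5, and for core B-lineage genes between 0 and 1. Lower counts ran between 0 and 1 for autophagy, 2 and 4 for core B-lineage genes, 0 and 5 for neutrophil and 0 and 2 for monocyte markers. In 10 lists, none of them called, the median, the mean and the direction of the test differed in sign.

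Camera in its main setting called no list of energy metabolism. None of 65 genes of oxidative phosphorylation, 18 of the citrate cycle or 16 of fatty acid oxidation passed limma's threshold, over all probes or over the list alone, and their median log2 fold changes were 0.07, 0.04 and -0.0005. The camera adjusted p were 0.409, 0.873 and 0.873. Of 19 regulators of mitochondrial biogenesis 4 rose and none fell (4 over the list alone, camera adjusted p = 0.309), Ppargc1a and its relative Ppargc1b (0.91) among them. Of 16 glycolysis genes 3 rose (3 over the list alone, adjusted p = 0.293), with Pfkp, a phosphofructokinase gene, at 0.85 and at 0.35 by its other tested probe. Of 13 hypoxia genes 6 rose and 2 fell (7 and 2 over the list alone, adjusted p = 0.119). Camera called this list with the probe of largest variance (0.0314), and fry gave it and the mitochondrial biogenesis list an adjusted p = 0.0442 each. For the lists of sterol synthesis (1 of 14 rose), nucleolar factors (1 of 21 rose) and other MYC targets (2 of 18 rose) the camera adjusted p were 0.915, 0.873 and 0.629, with 0, 0 and 2 higher adjusted over the list alone. Myc itself had a log2 fold change of 0.07 (SE 0.19, adjusted p = 0.858).

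Among genes of small pre-B and immature B cells, most of those called were lower on the arrays labelled Fnip1-null. Of 26 measured members 9 fell and 1 rose (10 and 2 adjusted over the list alone) and 16 did not pass, with a median of -0.24 and a camera adjusted p = 4.1e-05, or adjusted p = 0.189 with an estimated correlation. Cd22, an inhibitory coreceptor gene, fell by 1.84 (SE 0.12), and Blk, a pre-B cell receptor kinase gene, fell by 1.69 (SE 0.15), alongside Cd40. The other tested probe of Cd22 stood at -1.23. Il2ra, the interleukin-2 receptor gene of large and small pre-B cells, was at least 3.20-fold lower. Cxcr5, the member that rose, is a receptor of follicular B cells. The MHC class II genes of the list did not pass the threshold. Among 17 genes of the earliest B-lineage stages 4 rose and 4 fell, also over the list alone, with a camera adjusted p = 0.732. Rag1, the recombinase gene, fell by 2.06 (SE 0.11, adjusted p = 7.38e-06), whereas the transcription factor gene Lef1 rose by 0.92 and the stem cell factor receptor gene Kit by 1.01 on the log2 scale. The call of Kit was lost without array B labelled Fnip1-null (0.94) and without array B or C labelled wild type (0.93 and 0.90), and also with no detection filter. Dntt (0.57, adjusted p = 0.143), Igll1 (0.36, 0.220), Il7r (0.18, 0.470) and Vpreb1 (0.12, 0.527) did not pass, although without array A labelled wild type Dntt (0.84) and Igll1 (0.56) did, as did Dntt with a block on sex (adjusted p = 0.048). Of 15 core B-lineage genes 4 fell and 1 rose (5 and 2 over the list alone, camera adjusted p = 0.293), and Vpreb3, a pre-B cell receptor chaperone gene, fell by 0.92. Of 21 genes of pre-B cell receptor and interleukin-7 signalling 6 rose and 2 fell (7 and 4 over the list alone, adjusted p = 0.907), with Pik3cd, a phosphoinositide 3-kinase subunit gene, at 1.28 and the kinase gene Pim2 at -1.05. The other tested probe of Pim2 stood at only -0.19.

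**Figure D2:**
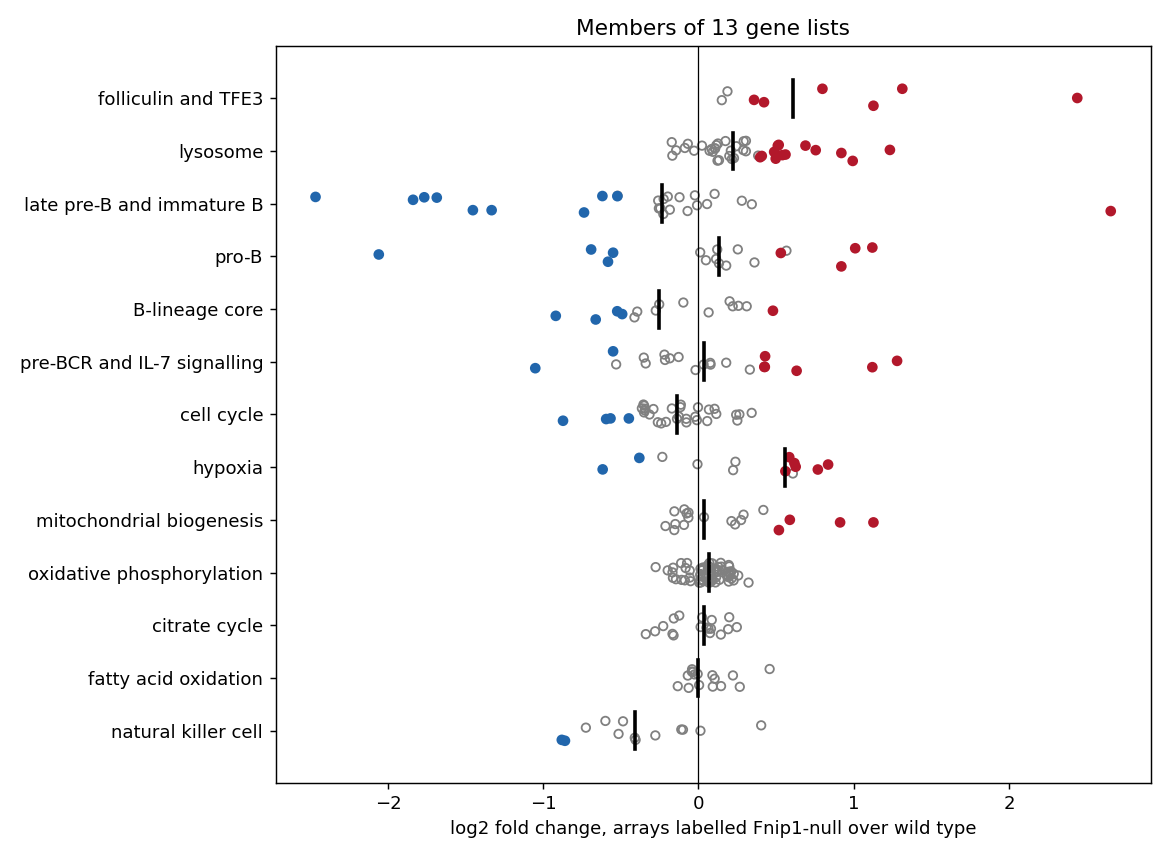
Log2 fold change (horizontal axis, arrays labelled Fnip1-null over wild type) of the measured members of 13 gene lists. Filled points passed an adjusted p under 0.05 (red higher, blue lower), open points did not, and the vertical bar is the list median, which is 0.61 for the folliculin list and -0.24 for the late pre-B list.

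Of 33 cell cycle genes 4 fell and none rose (4 over the list alone), among them E2f2, a transcription factor of S phase entry, at -0.87. With 1 array left out the number that fell was between 1 (without array B labelled Fnip1-null or array C labelled wild type) and 6 (without array C labelled Fnip1-null), and of the 4 only E2f2 kept its call in every such fit, while Cdc20, Tpx2 and Birc5 did not. The list median was -0.14, with a camera adjusted p = 0.0251 and an adjusted p = 0.941 with an estimated correlation. The camera call was lost without array A (0.130) or B (0.104) labelled Fnip1-null and without array C labelled wild type (0.184). Of 17 p53 targets 4 rose and 2 fell (5 and 2 over the list alone, adjusted p = 0.593), with Plk2, a polo-like kinase gene, at 2.24 and the cell cycle inhibitor genes Gadd45a and Cdkn1a at -0.92 and -0.82. Bcl2l1, which encodes the survival protein BCL-XL, fell by 1.30 (SE 0.13, adjusted p = 0.000328) among 18 apoptosis genes of which 2 rose and 1 fell, also over the list alone (camera adjusted p = 0.873). Other tested probes of Bcl2l1 stood at -0.79 and -0.70. In the stress lists, 3 of 21 integrated stress genes rose and 1 fell (3 and 1 over the list alone, adjusted p = 0.873), with the pseudokinase gene Trib3 at 1.44, and 3 of 14 antioxidant genes rose (3 over the list alone, 0.427), with the glutathione transferase gene Gstm1 at 1.47. Other tested probes gave smaller values, 0.38 and 0.51 for Trib3 and 0.51 for Gstm1. None of 16 unfolded protein response genes passed (0.629). Of 14 FOXO targets 3 rose and 1 fell (3 and 3 over the list alone, 0.907), the homing receptor gene Ccr7 at 1.46 and the repressor gene Bcl6 at -1.05. Of 19 interferon genes 2 rose (2 over the list alone, 0.920) and of 19 immediate-early genes 1 rose and 3 fell (1 and 4 over the list alone, 0.309), a list that camera called without array A labelled Fnip1-null (0.00715).

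Markers of other cells that the gate could hold were followed as measured facts beside these groups. Of 13 natural killer cell markers 2 fell and none rose (5 fell over the list alone, and between 0 and 5 fell with 1 array left out, the fewest without array A labelled Fnip1-null and the most without array C labelled wild type), with a median of -0.41, a camera adjusted p = 0.0209 and an adjusted p = 0.941 with an estimated correlation. The camera call was lost without array C labelled Fnip1-null (0.0965) or array A labelled wild type (0.109). Of 16 neutrophil markers 2 fell (1 over the list alone, adjusted p = 0.309), of 15 monocyte markers 1 rose and 2 fell (2 and 2, 0.593), and of 8 erythroid markers 1 fell (1, 0.629). Among 9 markers of basophils, mast cells and eosinophils 1 rose and 2 fell (1 and 3, 0.343). Camera called the neutrophil, erythroid and basophil lists lower without array A labelled Fnip1-null (0.000106, 0.00457 and 0.00618), and the neutrophil list also without array C labelled wild type (0.0249) and with array weights (0.0171). The basophil protease genes Mcpt8 and Prss34 stood at -1.03 and -1.33 while Hdc rose, and Prss34 lost its call without array C labelled wild type (-1.17). Of 13 T cell markers 3 rose and 1 fell (3 and 1, 0.381), Lat among those that rose. Cd8b1 rose by 0.58 by its brightest probe but stood at -0.84 (adjusted p = 0.395) by its probe of largest variance, so its direction is not settled. None of 14 plasmacytoid dendritic cell markers passed (0 over the list alone, 0.915), none of 6 plasma cell markers (1 lower, 0.539) and none of 3 stromal markers (1 lower, 0.595). Of 4 megakaryocyte markers 1 fell (2, 0.309) and of 10 stem and progenitor markers 1, Kit, rose (1, 0.915). Xist was detected on 2 of 3 arrays in each group, B and C, and neither of 2 sex-linked genes passed (camera adjusted p = 0.915). The SE of Xist was 1.83, since each group mixes arrays with and without it. On arrays B and C its brightest probe stood at 10.78 and 10.78 (labelled Fnip1-null) against 9.50 and 9.83 (labelled wild type). Its other probes differed in the same direction there, which was not tested. Of 9 measured neighbours of Fnip1 on chromosome 11, 4 rose and none fell (4 over the list alone), Kif3a by 0.80 and Rad50 by 0.74 on the log2 scale. The others, Rapgef6 and Slc22a5, were not steady: without array C labelled wild type 3 neighbours kept the call, and without any other single array 2. Camera gave this list an adjusted p = 0.0304, or adjusted p = 0.551 with an estimated correlation, and the call was lost without array A labelled wild type (0.0684).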

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

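Fnip1 stayed higher on the arrays labelled Fnip1-null under all 19 alternatives (log2 fold change 0.87 to 1.00, adjusted p = 5.61e-05 to 0.0221). The number of called genes was 685 (404 higher, 281 lower) with a fold of at least 1.5, 501 (307 and 194) at an adjusted p under 0.01, and between 731 and 915 (428 to 548 and 303 to 393) with 1 array left out, where fewer arrays enter the fit. No other scaling moved the share of higher calls by over 10 percentage points or the median of all genes by over 0.1. The gap between the lowest correlation within and the highest between groups (0.0123) was 0.00999 with normexp and an offset of 50, 0.0170 in the series matrix values, 0.00552 with no filter, 0.00873 with the strict filter and 0.00950 to 0.0134 with 1 array left out. With an estimated correlation 0 lists were called, and adjusted p was 0.189 for the folliculin and late pre-B lists, 0.941 for the lysosome, cell cycle and natural killer lists and 0.551 for the Fnip1 neighbours. The neighbours also lost the call with median scaling (0.0617), the mean of a gene's probes (0.0508) and the block below, the natural killer list with the strict filter (0.0925) and the cell cycle list with array weights (0.104). The cause was not tested. With 1 array left out adjusted p ran from 0.000381 to 0.184 for the cell cycle, 0.00086 to 0.109 for natural killer genes and 0.0142 to 0.0684 for the neighbours, while the folliculin, lysosome and late pre-B lists kept their calls. Of all 174 genes named by rule besides Fnip1, printed or not, 110 were called: 60 of these kept call and direction under every alternative in which they were tested and 50 lost the call under at least 1 (38 of them with 1 array left out). Of the 64 not called 26 gained a call under at least 1, and 30 genes were tested under fewer than all 19 alternatives. Cd8b1 reversed, from 0.58 to -0.84 with the probe of largest variance. Signal over background limits genes near the detection level, where folds are compressed.

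Whether the replicate numbers pair the arrays is not settled: in the series matrix values, same-numbered arrays' deviations from their group means correlated at 0.17, -0.003 and 0.23. Differently numbered arrays' deviations correlated between -0.24 and 0.07, so the values of 0.17 and 0.23 lay above all of these. As an alternative chosen after seeing the data, the replicate block on those values called 626 genes (376 higher, 250 lower) against 907 without the block, with an adjusted p of 0.0585 for the neighbours and the same correlation gap of 0.0170. A block on sex by Xist on the main values, also chosen after seeing the data, called 1423 genes (847 higher, 576 lower) and the same 6 lists, and left Fnip1 at 0.95.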

Other observations

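The tests of the lectin gene region's natural killer transcripts, of neighbouring genes around Fnip1, of mislabelling and of the mix of B-cell stages, and the splits of the arrays, were chosen only after the results they concern were seen. The test of normalization was written before its outcome. Some tests were also reworked after a first version had been run: that for a mislabelled array first compared the gap at the Fnip1 probes with the range within a group and was not met at 1 probe, and that for mature B cells first passed only through a wide standard error. The tests on mature B cells and on lower natural killer genes then compared against genes picked for having fallen, and now take all measured members. The test of gene order first used 1 window size and few shuffles, and its outcome moved across its threshold with the random numbers. The genes in the next paragraph were also chosen after their values were seen.

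Single genes outside the fixed lists, picked by eye and with no test of any group, include some of amino sugar metabolism and of the lysosome. Renbp, which encodes the renin-binding protein that epimerises N-acetylglucosamine, rose by 2.17 on the log2 scale (SE 0.14, limma adjusted p = 1.84e-05), the glucosamine-phosphate isomerase gene Gnpda1 by 1.63 and the kinase gene Nagk by 0.68. The lysosomal protease genes Lgmn and Dpp7 rose by 1.77 and 1.62, the cystine exporter gene Ctns by 1.17, the vacuolar ATPase subunit gene Tcirg1 by 1.02 and the Rag GTPase gene Rragb by 1.12. Among inhibitory receptor genes of B cells, Siglecg stood at -1.19 and Fcgr2b at -1.01, beside Cd22. Prodh and Dgcr6, both among the largest rises, lie next to each other on chromosome 16.

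The first pattern is the higher Fnip1 signal on the arrays labelled Fnip1-null. One mislabelled array would correlate with the other group, but the lowest correlation within a group was 0.0123 above the highest between groups, and the lowest Fnip1 log2 fold change over other background corrections and normalizations was 0.90, so neither accounts for it. The gap between the groups was positive at every detected Fnip1 probe, though at 1 of them (0.40) it was smaller than the range within a group (0.59). Linked variation around Fnip1 cannot be told apart from an effect on Fnip1 itself: 7 of the nearest 50 tested genes were called against a median of 6, and 46.3% of windows elsewhere held as many. An exchange of both groups' labels as a whole, under which the called folliculin-list and lysosomal genes would be lower in Fnip1-null cells, stays open. So does a transcript that persists from the mutated gene and may rise with Flcn and Rragd, a hypothesis that was not tested. The sources used here do not place the probes on the gene.

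The second pattern is the lower signal of late pre-B and immature B cell genes, with Cxcr5 going the other way. Fewer recirculating mature B cells in the sorts labelled Fnip1-null would lower their markers alike, though such cells mostly lack CD43 and the gate should remove most of them. The 5 detected markers had a median log2 fold change of -0.25 (SE 0.69, wide because of Cxcr5), as did the 23 other measured list members (-0.25), and the probes of Ms4a1, Cr2 and Bank1 were not detected on any wild-type array. The median of the detected markers is the value of Ccr6. Its mean signal (4.96), like that of Fcer2a (5.04), lay near the detection level, where folds are compressed. That explanation cannot be told apart from a change within cells, and neither can fewer cells of later B stages within the gate, for which the pro-B list, with a median of 0.13, moved both ways. The genotype, a block in development or a change in each cell may each take part, and sorted bulk RNA does not separate them.

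The third pattern is a run of changed genes in the natural killer gene complex on chromosome 6. There 9 of 24 tested Klr, Clec2 and Cd69 genes were called. The 4 higher were Clec2m (by 2.12), Cd69, Clec2d and Clec2i, and the 5 lower were Klra4 (at -1.93), Klri2, Klrb1f, Klre1 and Klrc1. Klre1 lost its call under 13 of 19 alternatives, and the other called genes were not followed. Clec9a, Clec1a and Clec7a, tested in the same stretch, were not counted among the 24 and did not pass. A window of 15 tested genes as dense in called 2-fold changes turned up in 3.6% of 2000 shuffles of gene order, but the window size was set after the region was noticed, and the share varied with it: 1% with windows of 5 genes, 13.9% with 10, 0.95% with 20, 2.2% with 25, 5.9% with 30 and 0% with 40. It lay under 5% at 5 of 7 sizes but not at all of them, and the sizes count overlapping genes, so they are not separate tests. Shuffling also breaks up families of neighbouring genes, so the test does not decide on chance order. Fewer natural killer cells do not account for the higher genes, of which there were 4. For the lower ones they stay open: natural killer transcripts from outside the complex had a median of -0.34 (SE 0.15) against -0.55 for all 19 tested Klr genes, while the abundant Prf1, Nkg7 and Ccl5 stood at 0.01, -0.51 and -0.28. Differences in strain background around the locus and signal shared between family members were not tested and stay open beside the genotype.

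With 10 splits of the 6 arrays, no share under 0.05 can be reached. The real split called 1270 genes and the highest of the others 0, so 1 of the 10 splits gave as many. The other splits each mix the groups, which adds the difference between groups to their spread, so few called genes were likely there from the start. For the gene lists the real split called 6 and the highest of the others 11, and 7 of the 10 splits gave at least as many. Lists whose genes vary together between arrays, such as the neutrophil markers, were called in up to 7 of the other splits, so the count of called lists carries little information on the genotypes.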
